A study of Mus musculus with 6 samples.

How the data were processed

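The series measured bulk RNA in CD11b+ cells that were sorted from mouse spleen by flow cytometry. The 6 libraries fall into 2 groups of 3 per the labels, MI (myocardial infarction) and MI+RDN (myocardial infarction with renal denervation). RNA was taken with a Qiagen column kit and strand-specific TruSeq libraries were read on an Illumina NovaSeq instrument, per the labels' protocols. The processing notes of the submitters name FastQC 0.11.2, the aligner STAR and the genome build GRCm39. The tool that counted reads per gene, the annotation release, the strand setting and the treatment of reads that map to more than 1 place are not given in the sources used here.

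The authors deposited a single table of counts per Ensembl gene with 1 column per library. Its values are whole numbers that carry no normalisation. The table holds 55335 genes, of which 31020 had 0 counts in all libraries. Symbols were matched by Ensembl ID from a reference annotation of an older build, GRCm38, and 55154 of the IDs had one. No coordinates are given because the builds differ. Library totals ranged from 21663440 to 28013900 counts, and the common biological coefficient of variation between libraries of a group was 20.7%. P-values describe the spread between these 6 libraries.

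Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr at its defaults, which left 14849. Library sizes were scaled with TMM factors, and MI+RDN was compared with MI by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. All 6 libraries entered the fit with no covariates. Fold changes are MI+RDN over MI, with standard errors taken as the absolute log2 fold change over the square root of F. Levels are CPM, counts scaled by library sizes that TMM factors had adjusted, as mean ± SD with n = 3. Principal components used log2 CPM with a prior count of 2 for the 500 most variable genes.

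A set of 45 gene lists was fixed before the data were examined. They cover functions of myeloid cells, markers of the cell types that a splenic CD11b+ gate does or does not hold, and technical groups such as ribosomal, mitochondrial and histone genes. Each list with at least 4 measured members was tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. The lists share some genes, for example Ciita in both the MHC class II and the conventional DC2 lists and Ly6g in both neutrophil lists.

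The genes named in the text follow a rule that was also fixed before the data were examined. It takes Itgam and Adrb1, among others. It adds up to 12 genes in each direction with the largest log2 fold change among those past the threshold, with a mean of at least 1 CPM and groups that do not overlap. Predicted genes, pseudogenes and antigen receptor segments were left out of that part. From each list it takes up to 4 passing members with the lowest p, or 2 members where none pass. Genes named outside this rule are marked as such.

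Alternatives fixed in advance were DESeq2 size factors, upper-quartile factors, no scaling factors, no filter, a filter at a mean of 5 CPM, the DESeq2 1.42.0 Wald test, limma-voom, robust edgeR, the replicate number as a block, removal of antigen receptor, haemoglobin and mitochondrial genes, and each library left out in turn. Added after seeing the data were offsets for transcript length and for GC content, and the mean of the B cell markers as a covariate. Transcript length and GC content came from the GRCm38 transcripts by gene ID and were found for 99.9% of tested genes. All 10 splits of the 6 libraries into groups of 3 were refitted. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

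The procedure was tested on simulated data, with 5 sets of counts for the 14849 genes drawn from the means and library sizes of this comparison and 200 genes changed in each. The edgeR test recovered 49.0% of genes changed 2-fold and 83.4% of those changed 4-fold, and 6.37% of its calls were false. A seeded list was called by camera in 5 of the 5 sets. With no change simulated, at most 4 genes and 0 lists were called. Simulated genes varied independently of each other, so the 0 lists does not hold for lists whose members vary together. In the real libraries, the 9 other splits gave 9 to 23 lists by camera at its preset correlation. Genes with close paralogs, such as the Stfa, Cd209, Ly6c, Hbb, Hspa1 and H2 families, and genes that overlap others are uncertain because the handling of shared reads is not known.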

Results

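Gene expression was measured by RNA sequencing in CD11b+ cells sorted from mouse spleen after myocardial infarction (MI) or after MI with renal denervation, the ablation of the nerves that run to the kidney (MI+RDN). CD11b, the product of Itgam, is carried by neutrophils, monocytes and macrophages, and by some dendritic, NK and B cells. Each group had 3 biological replicates, 6 libraries in all. The labels do not say how long after MI the cells were taken, or whether a replicate was 1 mouse or a pool. The MI libraries held 22662224, 21663440 and 24677865 counts, and the MI+RDN libraries held 27712146, 28013900 and 24634555. Spearman correlations between libraries across genes, which are not independent replicates, were 0.986 to 0.989 within MI, 0.980 to 0.986 within MI+RDN and 0.974 to 0.984 between the groups. The first principal component held 25.5% of the variance, with MI libraries from -23.7 to -4.97 and MI+RDN libraries from 3.18 to 22.2. The second held 22.2% and set MI+RDN replicate 3 (29.6) apart from MI+RDN replicate 2 (-17.4).

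The comparison of MI+RDN with MI asks how renal denervation alters the splenic myeloid cells of mice with an infarct. By camera at its preset correlation, the neutrophil and Ly6C-high monocyte lists were higher in MI+RDN and the MHC class II, conventional DC2, T cell and B cell lists were lower, and none of them passed with an estimated correlation (Benjamini-Hochberg adjusted p = 0.213 to 0.309). The members past the threshold over all genes were 4 of 24, 2 of 18, 8 of 17, 6 of 20, 2 of 26 and 0 of 24, in that order. Ly6g, the surface marker of mouse neutrophils, rose 2.92-fold, from 43.6 ± 10.5 CPM in MI to 127 ± 38.0 in MI+RDN (SD, n = 3). Ly6c2, a marker of inflammatory monocytes, rose 1.89-fold, from 369 ± 39.4 to 698 ± 73.9 CPM. Ciita, the master regulator of MHC class II transcription, was 2.23-fold lower, at 82.2 ± 6.35 CPM against 183 ± 24.2. Cd209a, a C-type lectin used here as a marker of CD11b+ dendritic cells, was 4.43-fold lower, at 26.1 ± 8.83 CPM against 116 ± 44.1.

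With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 150 of 14849 genes passed, 44 higher and 106 lower in MI+RDN. Of these, 80 changed at least 2-fold, 21 higher and 59 lower. In all 150 genes the groups did not overlap, as in 26.2% of all tested genes, where chance gives 10%. At an unadjusted p under 0.05 there were 2959 genes, against 742 by chance. The count fell with any 1 library left out, in fits with fewer samples. It was 18 without MI replicate 1, 4 without MI replicate 2 and 0 without MI replicate 3. It was 0 without MI+RDN replicate 1, 67 without MI+RDN replicate 2 and 36 without MI+RDN replicate 3. Whether the fall came from the library removed or from the smaller number of samples was not tested. The 2 counts of 0, also by edgeR, went with 2084 and 2323 genes at an unadjusted p under 0.05. Without scaling factors, 62 genes were higher and 413 lower, with the median of all genes moved to -0.13 on the log2 scale.

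**Figure D1:**
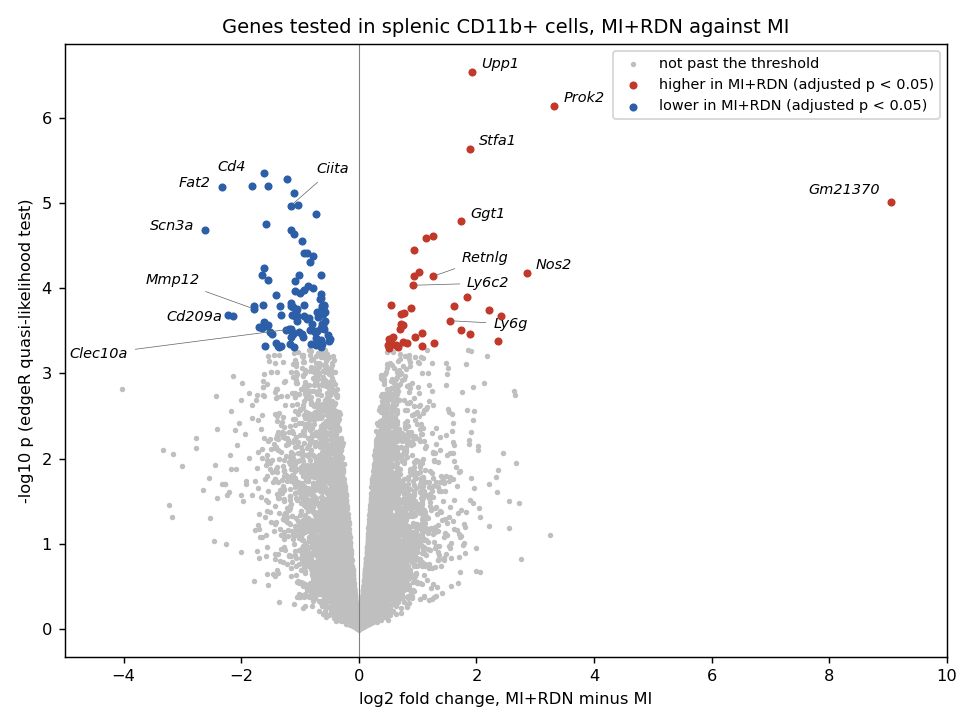
Log2 fold change of MI+RDN over MI (horizontal axis) against -log10 of the edgeR p-value (vertical axis) for the 14849 genes tested, with genes past the threshold in red (44 higher) and blue (106 lower). Upp1, Prok2 and Stfa1 have the lowest p among the labelled genes, and Gm21370, named after its values were seen, lies far right because it had 0 counts in all MI libraries, so its plotted fold depends on the prior count.

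Itgam, which encodes the sort marker, stood at 1133 ± 150 CPM in MI and 1598 ± 95.2 in MI+RDN (SD, n = 3), a log2 fold change of 0.50 that did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.109). Among the genes with the largest rise was Prok2 (ENSMUSG00000030069), a secreted chemoattractant made by neutrophils, which rose 9.99-fold from 1.27 ± 0.348 to 12.7 ± 1.47 CPM (log2 fold change 3.32, SE 0.236, edgeR Benjamini-Hochberg adjusted p = 0.00537). Upp1 (ENSMUSG00000020407), which encodes uridine phosphorylase, had the lowest p and rose 3.78-fold from 11.9 ± 1.34 to 44.9 ± 3.28 CPM (log2 fold change 1.92, SE 0.121, edgeR Benjamini-Hochberg adjusted p = 0.00427). Nos2, the inducible nitric oxide synthase, rose from 0.594 ± 0.231 to 4.33 ± 1.22 CPM, a 7.24-fold change at a low level. The acute-phase gene Saa3 rose 3.56-fold from 17.3 ± 6.11 to 61.5 ± 12.8 CPM. The stefin gene Stfa1 rose 3.71-fold, and its close paralog Stfa2, with which it may share reads, rose 5.19-fold. Ggt1, a gamma-glutamyltransferase of glutathione breakdown, rose 3.33-fold from 4.19 ± 0.607 to 13.9 ± 2.26 CPM. The other genes in the upper 12 were Ambp, Gpr27, Rhov, Dnah6 and AC134576.3, with log2 fold changes from 1.62 to 2.42.

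Among the lower genes, Scn3a, a voltage-gated sodium channel subunit, was 6.15-fold lower, at 0.453 ± 0.0627 CPM against 2.83 ± 0.355. The atypical cadherin Fat2 was 5.04-fold lower, at 1.34 ± 0.239 CPM against 6.77 ± 0.546. Cd209c, a C-type lectin and paralog of Cd209a, was 4.70-fold lower. Cd4 was 3.53-fold lower, at 10.8 ± 0.923 CPM against 38.1 ± 8.49 (log2 fold change -1.82, SE 0.172, edgeR Benjamini-Hochberg adjusted p = 0.0119). Mmp12, the macrophage elastase, was 3.44-fold lower, at 2.24 ± 0.701 CPM against 7.74 ± 1.36. Adam22, Akap2, Adgrl3, Celf4, Fndc7 and Hap1 had log2 fold changes from -1.78 to -1.62.

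MHC class II antigen presentation genes formed the list with the lowest p by camera at its preset correlation. With an estimated correlation or fry, the lowest unadjusted p was that of the Ly6C-high monocyte markers (0.0137 and 0.00112). Of 17 measured MHC class II members, 8 fell, 0 rose and 9 did not pass. Adjusted over the list alone, 13 were lower. The median log2 fold change was -0.93 (camera, Benjamini-Hochberg adjusted p = 8.44e-22, and adjusted p = 0.213 with an estimated correlation). H2-Eb1, a beta chain of the class II molecule, was 2.21-fold lower, at 495 ± 43.3 CPM against 1095 ± 233. H2-Eb2 was 2.22-fold lower, and H2-DMb2, part of the peptide-loading complex, was 1.91-fold lower.

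Conventional DC2 genes, which mark the CD11b+ dendritic cells, fell in 6 of 20 members, with 0 higher and 10 lower adjusted over the list alone. Their median log2 fold change was -0.73 (camera, Benjamini-Hochberg adjusted p = 6.88e-12, and adjusted p = 0.220 with an estimated correlation). Beside Ciita and Cd209a, Zbtb46, a transcription factor of conventional dendritic cells, was 2.22-fold lower, at 9.997 ± 0.827 CPM against 22.2 ± 4.63. Clec10a was 2.23-fold lower, at 18.4 ± 1.02 CPM against 41.2 ± 11.6. Without MI replicate 3 the conventional DC2 median was -0.48. The B and T cell lists were lower by camera beside both of these groups. T cell markers had a median log2 fold change of -1.02 over 26 members (camera, Benjamini-Hochberg adjusted p = 2.77e-17, and adjusted p = 0.260 with an estimated correlation). Of these members, 2 were lower (Cd4 and Cd3d), and 21 were lower adjusted over the list alone. Cd4 is not particular to T cells, as some splenic dendritic cells also carry it. In MI it stood at 38.1 ± 8.49 CPM, against 4.59 ± 0.740 for Cd3d. B cell markers had a median of -0.85 over 24 members, with 0 past the threshold over all genes and 20 lower adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 1.19e-16, and adjusted p = 0.309 with an estimated correlation). Relative to the mean of the 6 libraries on the log2 scale, B cell markers stood at -0.70, -0.61 and 0.097 in MI+RDN replicates 1 to 3. The lowest MI library, MI replicate 2, stood at 0.14, near MI+RDN replicate 3. Fcer2a, the low-affinity IgE receptor of B cells, stood at 25.1 ± 6.29 CPM in MI and 8.57 ± 2.98 in MI+RDN and did not pass.

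Other cell type lists were lower by camera at its preset correlation. Plasmacytoid DC markers had a median log2 fold change of -0.67, or -0.42 without MI replicate 3 (Benjamini-Hochberg adjusted p = 8.87e-04 by camera, and 0.309 as the adjusted p with an estimated correlation). Conventional DC1 markers, of a type that lacks CD11b, had a median of -0.50 (camera Benjamini-Hochberg adjusted p = 0.00727, 0.0550 without MI+RDN replicate 2, and adjusted p = 0.309 with an estimated correlation). Splenic macrophage markers had a median of -0.58, which was -0.37 without MI+RDN replicate 1 and -1.01 without MI+RDN replicate 3, with 9 of 23 lower and 2 higher adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 4.50e-05, and adjusted p = 0.431 with an estimated correlation). In that list Mrc1, the mannose receptor of red pulp macrophages, stood at 70.2 ± 19.6 CPM in MI and 26.9 ± 9.28 in MI+RDN, and did not pass (edgeR Benjamini-Hochberg adjusted p = 0.0571). NK cell markers had a median of -0.22 (camera Benjamini-Hochberg adjusted p = 0.0319, and adjusted p = 0.648 with an estimated correlation), T cell receptor segments -0.59 (0.0140 and 0.309) and erythroid markers -0.29 (0.0140 and 0.535). The NK call was lost without MI replicate 2, MI replicate 3 or MI+RDN replicate 1 (camera Benjamini-Hochberg adjusted p = 0.0913, 0.0701 and 0.462) and with the GC offset (0.0501). Its median was -0.10 without MI replicate 2 and -0.097 without MI+RDN replicate 1. It was -0.35 both without MI+RDN replicate 2 and without scaling factors. The T cell receptor call was lost without MI replicate 3 (camera Benjamini-Hochberg adjusted p = 0.0701, median -0.31), and its median was -1.25 without MI replicate 2, -1.09 without MI+RDN replicate 2 and -1.30 without MI+RDN replicate 3. The erythroid median had no stable sign. It was -0.00073 without MI replicate 1, 0.023 without MI replicate 2, 0.12 without MI+RDN replicate 1, -0.016 without MI+RDN replicate 2 and 0.022 without a filter, and the call was lost without MI replicate 2, without MI+RDN replicate 1 and without a filter (camera Benjamini-Hochberg adjusted p = 0.113, 0.265 and 0.286). It was also lost without antigen receptor, haemoglobin and mitochondrial genes (camera Benjamini-Hochberg adjusted p = 0.719, median 0.11), with limma-voom (0.0747) and without scaling factors (0.0574). No member of these 6 lists passed over all genes. Haemoglobin genes took 0.0393% to 0.0781% of counts in MI and 0.0164% to 0.0226% in MI+RDN.

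Neutrophil markers had positive fold changes in 24 of 24 members, with a median log2 fold change of 0.79 (camera Benjamini-Hochberg adjusted p = 6.46e-21, and adjusted p = 0.213 with an estimated correlation). Of these, 4 rose, and 15 were higher adjusted over the list alone. Retnlg, a resistin-like secreted protein, rose 2.39-fold from 546 ± 81.2 to 1307 ± 213 CPM, and Asprv1 rose 2.02-fold. The NADPH oxidase and phagocyte killing list was positive in 19 of 19 members with a median of 0.69, where Nos2 passed and 6 were higher adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 4.59e-08, and adjusted p = 0.309 with an estimated correlation). Without MI+RDN replicate 2, which stood highest for this list, its median was 0.30. Neutrophil precursor granule genes had the largest median of all lists, 1.11, with 1 of 21 past the threshold (Ly6g) and 3 higher adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 2.91e-07, and adjusted p = 0.466 with an estimated correlation). MI+RDN replicate 2 stood highest for these granule genes, 1.53 above the mean of the 6 libraries on the log2 scale, with the other MI+RDN libraries at 0.23 and -0.51. Without that library the median of the granule list was 0.23, so its size and its rank among the lists rested on that library.

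Ly6C-high monocyte markers had a median log2 fold change of 0.31, or 0.17 without scaling factors, with 2 of 18 past the threshold and 6 higher adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 4.26e-04, and adjusted p = 0.213 with an estimated correlation). The 2 were Ly6c1, which rose 1.92-fold, and Ly6c2, which are close paralogs. Ly6C-low monocyte markers, of the patrolling type, did not pass as a list (camera Benjamini-Hochberg adjusted p = 0.374). Pglyrp1 was its only member past the threshold and rose 1.94-fold from 211 ± 34.4 to 408 ± 66.9 CPM. Trem2, a lipid-sensing receptor of macrophages in the alternative activation list, rose 1.86-fold from 12.6 ± 0.259 to 23.4 ± 3.50 CPM, whereas Cd209a and Clec10a of the same list fell. That list did not pass (camera Benjamini-Hochberg adjusted p = 0.291), and its median of 0.0038 was opposite in sign to its mean and its test and turned to -0.027 with upper-quartile factors.

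**Figure D2:**
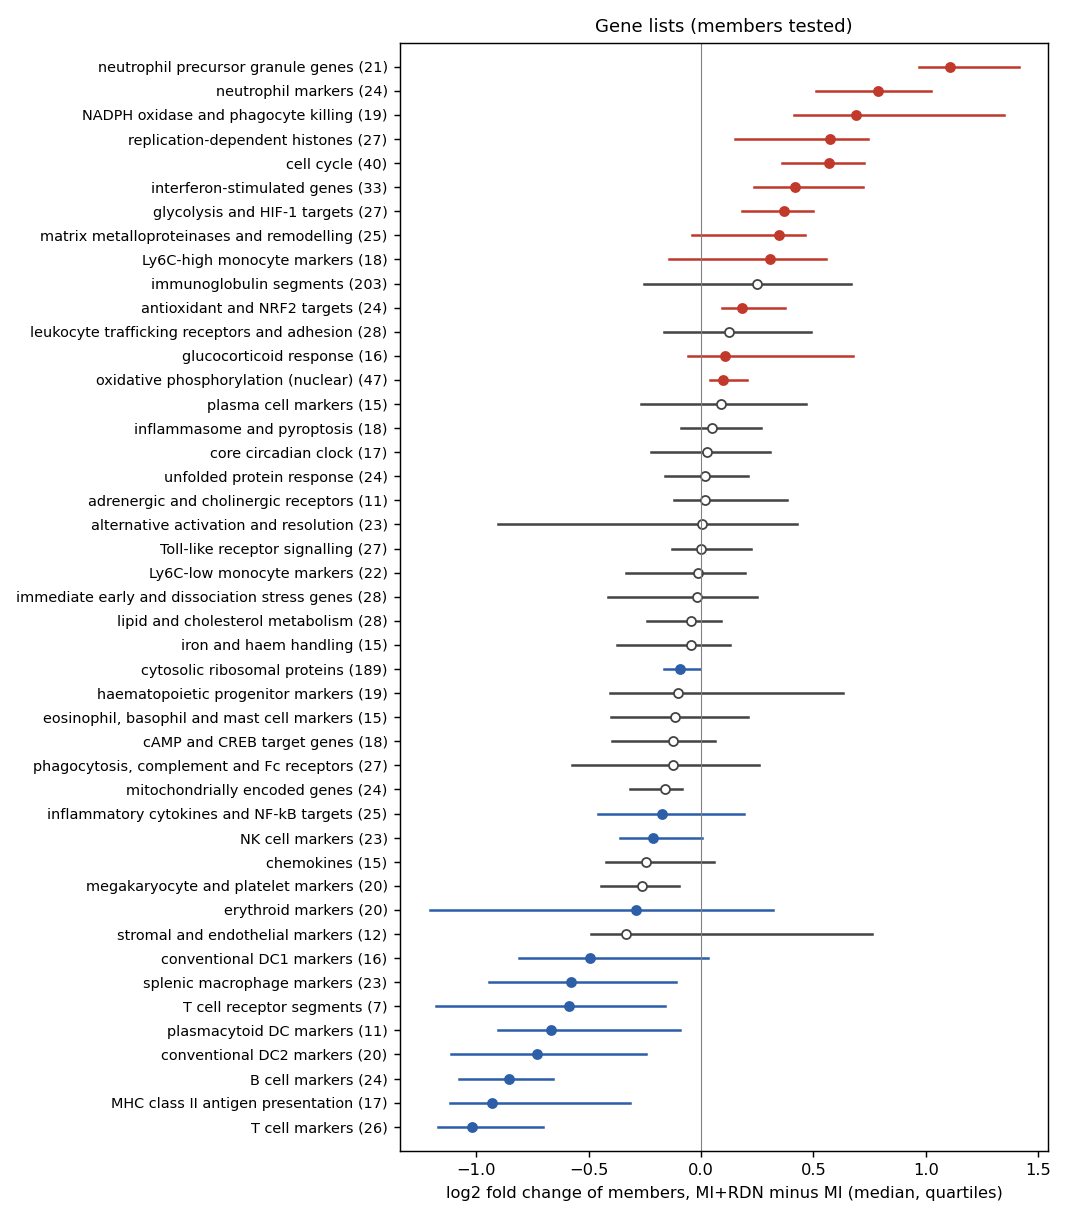
Median log2 fold change of the members of each of the 45 gene lists (points) with quartiles (lines), MI+RDN minus MI, with the number of tested members in brackets and filled points for lists past the camera threshold (12 higher in red, 12 lower in blue). Neutrophil precursor granule genes lie furthest right at 1.11 and T cell markers furthest left at -1.02, and without scaling factors the oxidative phosphorylation and glucocorticoid medians turn negative.

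Glycolysis and HIF-1 targets had a median log2 fold change of 0.37, with 0 of 27 past the threshold over all genes and 12 higher adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 8.46e-08, and adjusted p = 0.309 with an estimated correlation). That median was 0.24 without MI+RDN replicate 2 and 0.23 without scaling factors. Ldha, lactate dehydrogenase A, stood at 260 ± 13.7 CPM in MI and 365 ± 17.7 in MI+RDN, and Pgk1, phosphoglycerate kinase, at 142 ± 8.88 and 221 ± 36.1. Antioxidant and NRF2 targets had a median of 0.18, or 0.046 without scaling factors (camera Benjamini-Hochberg adjusted p = 0.00172, and adjusted p = 0.260 with an estimated correlation), and peroxiredoxin Prdx5 rose 1.69-fold from 294 ± 25.02 to 496 ± 71.0 CPM. Nuclear genes of oxidative phosphorylation had a median of 0.098, which turned to -0.040 without scaling factors (camera Benjamini-Hochberg adjusted p = 0.00765, and adjusted p = 0.648 with an estimated correlation). It was 0.16 without MI replicate 3 and without MI+RDN replicate 1 and 0.039 without MI+RDN replicate 2, and the call was lost without the last of these (camera Benjamini-Hochberg adjusted p = 0.196), without MI replicate 1 (0.0917), without scaling factors (0.0958) and with the transcript length offset (0.112). Glucocorticoid response genes had a median of 0.11, which turned to -0.032 without scaling factors (camera Benjamini-Hochberg adjusted p = 0.0481, and adjusted p = 0.636 with an estimated correlation). That call was lost without MI replicate 3 or MI+RDN replicate 3 (camera Benjamini-Hochberg adjusted p = 0.363 and 0.417), with limma-voom (0.106), with a mean of at least 5 CPM (0.0664), with DESeq2 size factors (0.0508), with the GC offset (0.0528) and without antigen receptor, haemoglobin and mitochondrial genes (0.0504). The median ranged from 0.032 without MI+RDN replicate 3 to 0.21 without MI replicate 2, with 0.17 without MI replicate 1, 0.18 without MI+RDN replicate 1 and 0.17 without MI+RDN replicate 2. Fkbp5, a glucocorticoid receptor cochaperone, stood at 85.4 ± 27.6 CPM in MI and 241 ± 70.0 in MI+RDN and did not pass (edgeR Benjamini-Hochberg adjusted p = 0.0574). Cytosolic ribosomal protein genes, a group that also takes in pseudogenes and ribosomal kinases, had a median of -0.095 (camera Benjamini-Hochberg adjusted p = 0.0350, and adjusted p = 0.785 with an estimated correlation). That call was lost without MI replicate 3 (camera Benjamini-Hochberg adjusted p = 0.898, median -0.0080), without MI+RDN replicate 1 (0.537, median -0.047), without a filter (0.0853) and with the replicate block (0.0569), and the median was -0.16 without MI+RDN replicate 2 and -0.23 without scaling factors.

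Inflammatory cytokines and NF-kB targets had a median log2 fold change of -0.18 over 25 members (camera Benjamini-Hochberg adjusted p = 0.0495, and adjusted p = 0.309 with an estimated correlation). The call was lost without MI replicate 1, MI replicate 2, MI+RDN replicate 1 or MI+RDN replicate 2 (camera Benjamini-Hochberg adjusted p = 0.0598, 0.194, 0.0891 and 0.0611), with DESeq2 size factors (0.0526), with limma-voom (0.0615) and without antigen receptor, haemoglobin and mitochondrial genes (0.0589). The median was -0.27 without MI+RDN replicate 1 and -0.32 without scaling factors. Against that direction, Nos2 was its only member past the threshold. Adjusted over the list alone, 8 members were lower and 2 higher. Matrix metalloproteinases and remodelling genes had a median of 0.35, or 0.22 without scaling factors, with 8 of 25 higher and 1 lower adjusted over the list alone (camera Benjamini-Hochberg adjusted p = 7.72e-04, and adjusted p = 0.213 with an estimated correlation). Its only member past the threshold over all genes was Mmp12, which was lower. Chemokines did not pass (camera Benjamini-Hochberg adjusted p = 0.130), nor did leukocyte trafficking receptors (0.0714), inflammasome genes (0.137) or Toll-like receptor signalling (0.801). In the last of these Tlr9, the endosomal DNA sensor, was 1.49-fold lower, at 35.2 ± 2.38 CPM against 52.6 ± 0.4996.

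Interferon-stimulated genes had a median log2 fold change of 0.42 over 33 members with 0 past the threshold (camera Benjamini-Hochberg adjusted p = 1.62e-05, and adjusted p = 0.636 with an estimated correlation). Without MI+RDN replicate 3 the median was 0.11 and the list did not pass (camera Benjamini-Hochberg adjusted p = 0.0574). Gbp2, an interferon-induced GTPase, stood at 95.3 ± 27.3 CPM in MI and 200 ± 68.8 in MI+RDN. Cell cycle genes had a median of 0.57 over 40 members with 0 past the threshold (camera Benjamini-Hochberg adjusted p = 5.15e-04, and adjusted p = 0.693 with an estimated correlation). That call rested on MI+RDN replicate 2, without which camera gave the opposite direction and did not pass (Benjamini-Hochberg adjusted p = 0.631). Replication-dependent histones had a median of 0.58 (camera Benjamini-Hochberg adjusted p = 0.00350, and adjusted p = 0.213 with an estimated correlation).

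Adrenergic genes were examined because the title of the series names a renal and splenic nerve axis. Adrb1, an adrenergic receptor, stood at 2.81 ± 0.104 CPM in MI and 4.49 ± 1.68 in MI+RDN and did not pass (edgeR Benjamini-Hochberg adjusted p = 0.246). The list of adrenergic and cholinergic receptors did not pass (camera Benjamini-Hochberg adjusted p = 0.509), nor did cAMP and CREB targets (0.392), immediate early and dissociation stress genes (0.338) or core clock genes (0.755). Kit, a receptor of progenitors and mast cells, was 1.65-fold lower, at 26.9 ± 1.98 CPM against 44.4 ± 5.85. Neither of its lists passed, haematopoietic progenitors (camera Benjamini-Hochberg adjusted p = 0.0699) or eosinophils, basophils and mast cells (0.463).

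**Figure D3:**
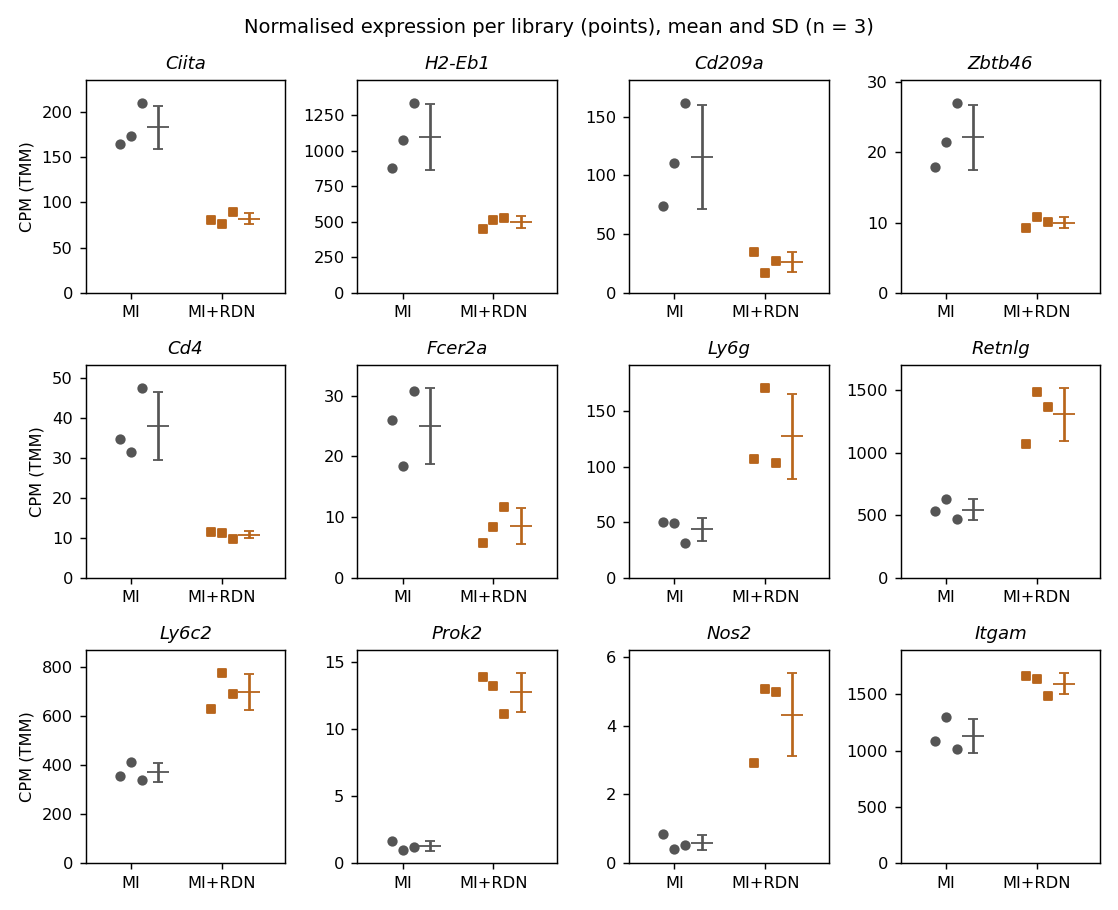
Normalised expression (CPM on TMM-scaled library sizes, linear axes from 0) of 12 genes in the 3 MI and 3 MI+RDN libraries (points), with mean and SD (lines). The groups do not overlap in any panel, and Fcer2a and Itgam are the panels that did not pass the edgeR threshold.

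Of the 45 lists, 24 passed with camera at its preset correlation, 12 higher and 12 lower. With an estimated correlation in camera, or with fry, 0 passed, and the lowest Benjamini-Hochberg adjusted p-values were 0.213 and 0.0506. At an unadjusted p under 0.05 there were 8 and 15 lists. The other 9 splits of the 6 libraries gave 9 to 23 lists with camera at its preset correlation, against the 24 here.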

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

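The offsets for transcript length and GC content and the B cell covariate were chosen after seeing the data. All 150 genes kept their sign under every alternative for which they had a value, and the counts of calls moved. These genes had passed in the same libraries, with groups that did not overlap and absolute log2 fold changes of at least 0.48. Kept signs were therefore likely from the start and say little about stability. Without scaling factors there were 475 calls (413 lower, 183 at least 2-fold). Without a filter, which tested 24315 genes, there were 21 (7 higher, 14 lower, 19 at least 2-fold), and with a mean of at least 5 CPM, which tested 10242, there were 290 (67 higher, 223 lower). The DESeq2 Wald test gave 1165 (561 higher, 604 lower, 264 at least 2-fold), 149 of them shared. Limma-voom gave 111, with 29 higher, and robust edgeR 277 (89 higher, 188 lower). Without antigen receptor, haemoglobin and mitochondrial genes there were 277 (84 higher, 193 lower). The length offset gave 47 (19 higher, 28 lower, 33 at least 2-fold). The B cell covariate gave 7, all higher and all at least 2-fold, with 0 lower by edgeR and 972 genes at an unadjusted p under 0.05. B cell markers differed between the groups, so this covariate takes up part of the group difference. The counts with DESeq2 size factors, upper-quartile factors and the GC offset were 123, 159 and 138. The cause of these moves was not tested, also where fewer or more genes entered the test.

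With 1 library left out, calls ranged from 0 without MI replicate 3 to 67 without MI+RDN replicate 2, where 2084 and 3267 genes had an unadjusted p under 0.05 (edgeR). Genes higher ranged from 0 to 30, genes lower from 0 to 37 and those at least 2-fold from 0 to 43, in fits with fewer samples. With the replicate number as a block there were 87 calls (23 higher, 64 lower), 55 of them shared. Deviations from the group means gave no sign that the numbers pair the samples. Deviations of samples with the same number correlated at 0.018, -0.065 and 0.064, and not every sample correlated best with its own number. With 3 libraries per group this check is weak, so whether the numbers mark a pairing stays unknown.

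Of the lists, 20 to 26 passed under the alternatives in camera at the preset correlation other than the B cell covariate, which gave 17, 11 of them shared. With an estimated correlation 0 passed, and with fry 0. Without MI+RDN replicate 2 the cell cycle list turned to lower (camera Benjamini-Hochberg adjusted p = 0.631), and over the libraries left out its adjusted p ranged from 6.00e-12 to that value. Under the B cell covariate, 6 lists that passed in the main fit or under the covariate changed direction. They were cell cycle (0.0742), neutrophil precursor granule genes (0.269), splenic macrophages (0.704), B cells (0.951), ribosomal proteins (0.269) and mitochondrially encoded genes (4.50e-05). A further 4 lists, which passed in neither fit, also changed direction under that covariate. The MHC class II (4.30e-09), neutrophil (4.30e-09), T cell (1.22e-05), conventional DC2 (7.49e-05) and Ly6C-high monocyte (0.00987) lists kept their calls there, and the NADPH oxidase (0.356), antioxidant (0.269), glucocorticoid (0.285), metalloproteinase (0.0515), conventional DC1 (0.399), plasmacytoid DC (0.320), NK cell (0.425) and T cell receptor (0.399) lists lost theirs in the same direction. Among named genes, 1385 comparisons with an alternative kept their side of the threshold, 334 no longer passed, 112 passed only under the alternative and 6 uncalled values changed sign. The self-test recovered 49.0% of 2-fold changes at this depth and spread, so many genes with changes of that size would be missed.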

Other observations

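The lists not yet described did not pass with camera and Benjamini-Hochberg adjustment: immunoglobulin segments (adjusted p = 0.136), lipid and cholesterol metabolism (0.204), mitochondrially encoded genes (0.219), megakaryocytes and platelets (0.360), phagocytosis, complement and Fc receptors (0.360), iron and haem handling (0.374), stromal and endothelial markers (0.760), plasma cells (0.860) and the unfolded protein response (0.883). Fasn, fatty acid synthase, stood at 38.7 ± 4.94 CPM in MI and 27.2 ± 2.09 in MI+RDN (SD, n = 3). The heat shock gene Hspa1b stood at 39.2 ± 15.6 and 14.8 ± 3.64 CPM, and the clock gene Per2 at 23.6 ± 8.24 and 47.1 ± 14.1 CPM. None of these 3 genes passed in edgeR.

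MI+RDN libraries differed from each other in several groups. Cell cycle genes stood 1.05 above the mean of the 6 libraries in MI+RDN replicate 2 on the log2 scale, with the other libraries from -0.42 to -0.06. Interferon-stimulated genes were highest in MI+RDN replicate 3 (0.66), as were immunoglobulin segments (0.89). Some genes, singled out after their values were seen, had 0 counts in all libraries of 1 group. Gm21370, a predicted gene, had 0 counts in each MI library and 71, 65 and 67 in MI+RDN, at least 64.0-fold higher against a floor of 3 counts over the group (edgeR, Benjamini-Hochberg adjusted p = 0.0133). Timd2 had 12, 17 and 10 counts in MI and 0 in each MI+RDN library, at least 13.8-fold lower by the same floor, and fell under the filter of the test. Gm12551 had 14, 10 and 14 counts in MI and 0 in each MI+RDN library, at least 13.4-fold lower (edgeR, Benjamini-Hochberg adjusted p = 0.0496). These bounds cover counting error only.

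Of the tests below, those of transcript length, of B and T cells, of MI+RDN replicate 2 and of other myeloid types were chosen after the results were seen. The split of the libraries into MI and MI+RDN gave 150 genes, and 1 of the 10 splits, the real one, gave as many, with 2 genes in the highest other split. For genes changed at least 2-fold it was also 1 of 10, with 80 against 2. For lists past camera it was 1 of 10, with 24 against 23. A design of 3 against 3 has too few splits for a share under 0.05. Genes called lower had longer transcripts (median 5050.5 nt) than genes called higher (1644.5 nt), against 2991 nt for all tested. With the length trend of each library taken out, the median absolute log2 fold change of the 150 genes was 0.97 against 1.04 before and their median SE 0.147 against 0.142. The calls went to 47, and what ended the others was not tested. Over deciles of length, the median log2 fold change of tested genes ran only from 0.067 to -0.074, so taking out the trend could move these genes little. These values argue against a length trend shared across genes as the whole cause of the fold changes. Length effects that differ between genes were not tested, and a part of the count of calls may rest on length.

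MHC class II and conventional DC2 genes were lower together with B and T cell markers, and B cells also express MHC class II. A trend with transcript length as the whole cause is argued against. The median log2 fold change of the 35 members was -0.74 before and -0.72 with the trend taken out. The 95% bootstrap interval of the latter was -1.07 to -0.41, over genes, which are not independent. The fit with the B cell covariate cannot decide whether fewer B cells are the whole cause. Its covariate is the mean of the B cell markers, so little is left in them by construction (median -0.22). The median of the 35 members was -0.46 in that fit (-0.59 to -0.28, over genes, which are not independent). There 0 genes passed as lower in edgeR, with 972 genes in both directions at an unadjusted p under 0.05. Whether fewer T cells add to the pattern, or conventional DC2 are a smaller share of the sorted cells, stays open as a candidate explanation. Of 12 conventional DC2 genes taken here as not shared with B and T cells, 3 fell (Cd209a, Clec10a and Zbtb46). The median over the 12 was -0.44, with an interval over genes from -1.06 to 0.076. Some of the 12 are not particular to conventional DC2. Notch2 (log2 fold change 0.39) is also expressed by some B cells, and Clec4a2 (0.42) and Clec12a (0.19) by other myeloid cells. The median therefore cannot decide whether the share of conventional DC2 changed. Lower expression per cell, a change in purity of the sort, which should remove T cells, and an effect of denervation itself were not tested apart.

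Neutrophil markers were higher, which may reflect a larger share of neutrophils among the sorted cells. The pattern did not come from MI+RDN replicate 2 alone, since the median log2 fold change was 0.69 without it and 0.79 with it. The 95% bootstrap interval without that library was 0.58 to 0.83, over genes, which are not independent. Fewer dendritic and lymphoid cells would raise all remaining myeloid types alike. The neutrophil median exceeded that of Ly6C-low monocytes by 0.80 (0.51 to 1.18, also over genes). Some genes of the Ly6C-low list, such as Klf2 and Itgal, are not particular to monocytes. Loss of lymphoid cells could lower that list too, so the difference cannot decide this. Whether the change lies in cell numbers or in expression per cell cannot be read from bulk libraries.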
